A study of Bos taurus with 8 samples.

How the data were processed

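Whole-genome bisulfite sequencing was applied to blood cell DNA of 8 female calves, 4 labelled high BHB and 4 labelled low BHB. Bisulfite converts unmethylated cytosine to uracil and leaves methylated cytosine in place, so that the share of reads with a cytosine gives the methylation level of a site. Per the labels' protocols, DNA was extracted with a Qiagen DNeasy kit, and bisulfite-converted libraries were made with the Pico Methyl-Seq kit. Trimmomatic, Bismark and methylKit, and the assemblies ARS-UCD1.2 and bosTau9, are named in the submitters' processing notes, without versions or parameters. The methylation level of a site does not by itself separate a C-to-T sequence variant from an unmethylated cytosine. This bears on every difference between small groups of animals.

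The values are the authors' own comparison of the groups, in the column format of methylKit per the file headers. One deposited table lists single cytosines in CpG context, and the other lists windows of 2000 bp placed at steps of 100 bp. Each entry holds a p-value, a q-value and a methylation difference that the authors computed, the last in percentage points. The p-values reached 1 in both deposited tables, so that the entries had not been selected by p-value or difference. The reference group of the difference, the coverage minimum, the treatment of overdispersion and the method behind the q-value are not given in the sources used here. The authors' q-values were 0.295 times (windows) and 0.790 times (cytosines) those from a Benjamini-Hochberg adjustment of their p-values, as medians. No column holds values of single calves, read counts or coverage, so the depth behind each value is unknown and no interval was derived from counts.

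The tests fixed before the data were examined used methylated and unmethylated counts per calf. They comprised models per window and per CpG, mean levels per calf, genomic contexts and 14 gene lists, each with calves left out, other splits of the calves, birth date as a covariate and other coverage minimums. None of them was run, since they need values per calf, gene positions on this assembly, or both. The fixed plan for deposited comparisons, a description by direction and size with stricter thresholds and without X, was followed instead. Genes and genomic contexts were not assigned, because the gene table at hand uses another assembly than the coordinates.

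Windows that shared bases were joined into runs. By the naming rule fixed before the data were examined, the 10 called entries with the greatest positive and the 10 with the greatest negative difference are named. After the overlap of the windows had been seen, the rule was applied to the most extreme window of each run, and the same rule was used for single cytosines, of which the text gives the foremost. The requirement that the groups do not overlap, and the parts of the rule on genes, could not be applied. Features called at q below 0.05 were counted by direction and at differences of at least 10, 15, 20, 25 and 50 percentage points. A standard error was derived from each difference and its two-sided p-value, where the p-value was above 0 and below 0.9, with a median of 1.11 percentage points for windows and 4.64 for cytosines. Cytosines at adjacent positions on opposite strands were paired as 1 CpG, and the differences of both were averaged where a CpG is treated as a unit. Ratios of differences were taken between a called CpG and other listed CpGs at set distances.

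Positions were tested by permutation. CpGs with at least 50 percentage points were shuffled 1000 times over the listed CpGs of their chromosome, and runs with at least 10 percentage points were shuffled over all runs of their chromosome, 10000 times for clustering and 1000 times for proximity to such CpGs. X was compared with the autosomes by a bootstrap of 1000 draws over blocks of 1 Mb. Chromosomes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment.

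Alternatives planned before the data were examined were a q-value below 0.01, differences of at least 10 or 25 percentage points, and autosomes alone. Added after seeing the data were a Benjamini-Hochberg adjustment of the authors' p-values, differences relative to the median, windows without overlap or 1 value per run, single strands, windows without a listed p-value of 0, the error multiplied by the scatter between strands, CpG means inside named windows, and thresholds of 25 and 40 percentage points for large CpG differences.

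The functions were tested on simulated cytosine tables of 40000 entries. With a change of 40 percentage points at some sites and no spread between calves, 97.5% of the changed cytosines and 26 unchanged cytosines were called. With an SD of 0.15 between calves in the methylation fraction and a model that ignores it, 3961 unchanged cytosines were called. The scatter between strands, relative to the error implied by the p-values, was 1.06 without and 1.01 with this spread at even coverage, and 1.07 without and 1.16 with it at uneven coverage. At highly methylated sites without this spread it was 1.14. It therefore reflects spread between calves at most in part. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.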

Results

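DNA methylation was measured by whole-genome bisulfite sequencing in blood cells of 8 female dairy calves (Bos taurus). The study concerns the metabolic status of the calves' dams, and the labels place 4 calves in a high BHB group and 4 in a low BHB group. BHB is read here as β-hydroxybutyrate, a ketone body whose blood level rises when a cow mobilises body fat around calving. The comparison of these groups asks whether the methylation of calf blood DNA differs with the metabolic status of the dam. Of the low BHB calves, 3 were born between 28 March and 5 April and the other on 18 August of the year before, while 3 of the high BHB calves were born between 3 July and 7 September and the other on 27 February. The values are the authors' group differences in percentage points for 2000 bp windows and for single CpG cytosines, with coordinates on the bovine assembly ARS-UCD1.2. No value per calf was analysed here, the depth is unknown, and which group was subtracted from which is not given in the sources used here, so that differences are described as positive or negative.

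Most of the tested windows carried a small positive methylation difference between the groups. In the authors' deposited table of 107232 windows, 93945 differences were positive and 13286 negative, with a median of 3.23 percentage points and an interquartile range of 1.46 to 4.99. The windows overlapped in 12539 runs that covered 35.9 Mb, with a median run length of 2600 bp, and windows of a run share reads. At a q-value below 0.05, the authors' deposited table called 84653 windows (78.9%), of which 78751 were positive and 5902 negative. The called windows lay in 10980 of the runs, 10135 of them with a positive call, 1154 with a negative call and 309 with both. Subtracting the median difference balances the signs of all windows by construction. Relative to it, 37038 windows were called at a Benjamini-Hochberg adjusted p-value below 0.05, and 50.9% of them were positive, against 93.0% as deposited. This count is over the windows whose p-value gave an error. With the same adjustment of the authors' p-values and no subtraction, 74794 windows were called, 94.1% of them positive.

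**Figure D1:**
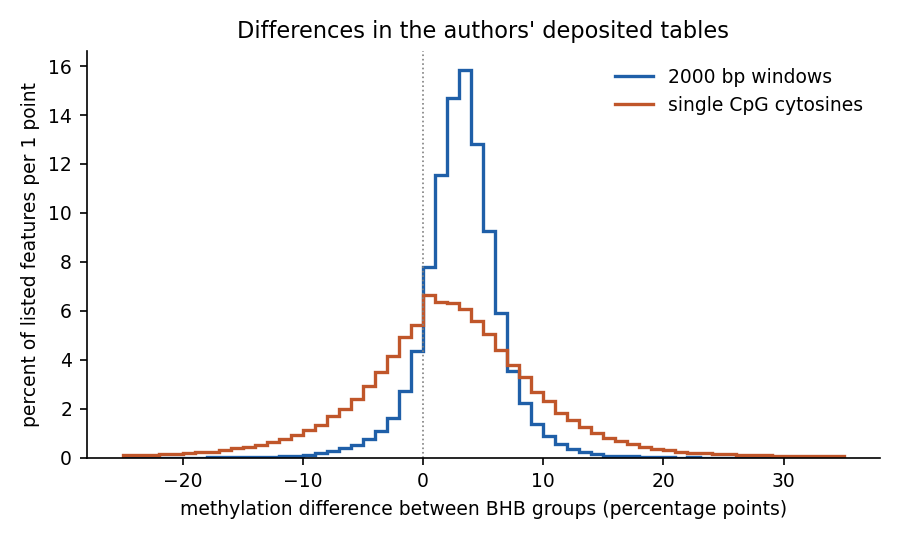
Distribution of the methylation difference between the BHB groups (x axis, percentage points) as the percent of all listed features in bins of 1 percentage point (y axis), for 2000 bp windows (blue) and single CpG cytosines (orange), with features outside the plotted range not drawn. Both medians lie to the right of 0, at 3.23 for windows and 2.13 for cytosines, while the cytosines spread more widely to both sides of 0 (63.1% positive).

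Differences of 10 percentage points or more were confined to a small part of the tested windows. They were found in 3071 of the called windows in the authors' deposited table, 2744 positive and 327 negative, which fell into 597 runs. The positive ones include the 84 windows on chromosome 27 and the 23 on chromosome 18 with a listed p-value of 0, described further below. These windows were not removed from the counts by size. At 15 percentage points 490 windows in 100 runs remained, at 20 percentage points 106 windows, and at 25 percentage points 15 windows in 5 runs, all of them positive. The share of positive windows was 89.4% at 10 percentage points and 82.2% at 15.

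The region with the greatest positive difference in the authors' deposited table lay on chromosome 13 at 21095901 to 21097900, with 30.8 percentage points (the authors' q = 6.6e-86). All 5 CpGs listed inside this window were positive, with a mean of 33.6 percentage points. On chromosome 8, the window from 49250701 to 49252700 differed by 29.4 percentage points in the authors' deposited table (the authors' q = 5.35e-97), and its 5 listed CpGs, all positive, had a mean of 36.3. Chromosome 1 held the next 3 positive regions of the authors' deposited table, at 60803201 to 60805200 with 27.4 percentage points, at 100617101 to 100619100 with 27.1 and at 33470201 to 33472200 with 25.1. Of their listed CpGs, 2 of 4, 7 of 8 and 4 of 4 were positive. In the first of these, the mean of the listed CpGs was 15.7 percentage points, and 7.43 without the CpG of greatest difference. The remaining 5 named positive windows in the authors' deposited table lay on chromosomes 7 (44710601 to 44712600), 2 (42624301 to 42626300 and 50525901 to 50527900), 11 (106737501 to 106739500) and 14 (54297301 to 54299300), with differences from 24.1 down to 22.4 percentage points. The mean of the listed CpGs was positive in all 10 named positive windows, although it rested on 1 CpG in the window on chromosome 11.

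The greatest negative difference in the authors' deposited table was found on chromosome 28 at 19583801 to 19585800, with -21.0 percentage points (the authors' q = 9.39e-46). None of the 3 CpGs listed inside it was negative, and their mean was 5.38 percentage points. These 3 CpGs lay between 19585599 and 19585725, near the end of the window, and so describe only that part of it. The overlapping window from 19584901 to 19586900, which also held them, differed by 1.59 percentage points in the authors' deposited table. The window on chromosome 7 from 85935501 to 85937500 differed by -20.9 percentage points in the authors' deposited table (the authors' q = 3.64e-27), and all 4 of its listed CpGs were negative, with a mean of -33.8. On chromosome 15, at 14461801 to 14463800, the authors' deposited table gave a difference of -20.7 percentage points (the authors' q = 1.04e-41), with 3 of 7 listed CpGs negative and a mean of -25.4. The 3 negative CpGs differed by -61.7, -65.3 and -69.0 percentage points, while the others lay between 1.26 and 6.36. The mean therefore rested on isolated CpGs with large differences. Windows on chromosome 8 at 33666701 to 33668700 and at 66451801 to 66453800 had differences of -18.7 and -18.0 percentage points in the authors' deposited table, and all 6 and all 7 of their listed CpGs were negative. Another window on this chromosome, at 23166301 to 23168300, also differed by -18.0 percentage points in the authors' deposited table, whereas its 3 listed CpGs were all positive with a mean of 11.1. The other named negative windows lay on chromosomes 2 (90865501 to 90867500, -19.6), 4 (58566101 to 58568100, -19.6), 24 (1841401 to 1843400, -17.9) and 27 (41079401 to 41081400, -17.2), with the authors' differences in percentage points in brackets. In the windows on chromosomes 2 and 27 the mean of the listed CpGs was above 0, at 0.973 and 1.09 percentage points. It was -9.35 on chromosome 4 and -9.95 on chromosome 24, and -1.17 and -5.07 without the CpG of greatest difference.

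**Figure D2:**
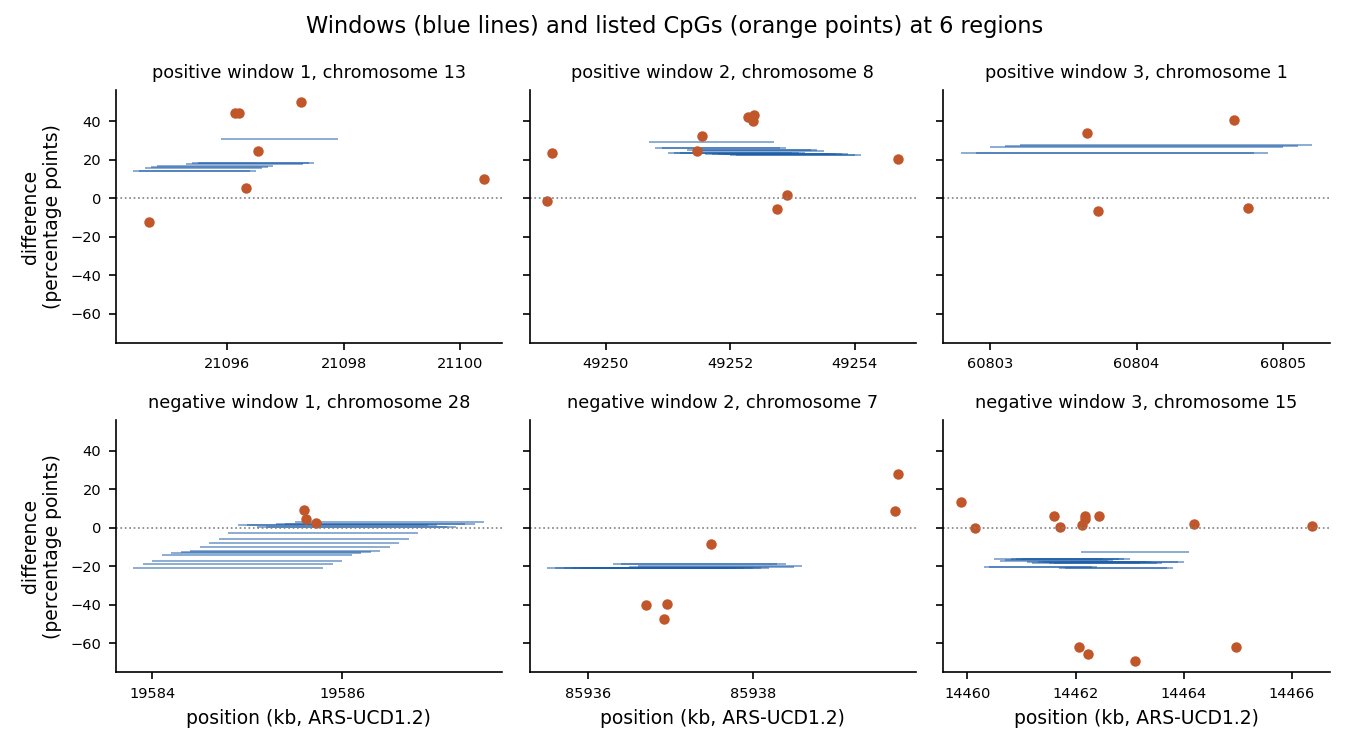
Methylation difference (y axis, percentage points) along the 3 named windows of greatest positive difference (top) and the 3 of greatest negative difference (bottom), with position in kb on the x axis; each blue line is a 2000 bp window and each orange point a CpG, both as listed by the authors. Windows and CpGs lie on the same side of 0 on chromosomes 13, 8 and 7 for most CpGs. On chromosome 28 the window of -21.0 holds 3 CpGs, all near its end, with a mean of 5.38.

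In most runs with a difference of 10 percentage points or more, the mean of the listed CpGs had the sign of the window, although single CpGs often did not. Of the 597 runs, 488 had at least 3 listed CpGs in their most extreme window, and the CpG mean had the sign of the window in 453 of them and the opposite sign in 35. All listed CpGs had the sign of the window in 165 of the 488. The median of the CpG means, counted toward the side of the window, was 9.32 percentage points, and 4.55 without the CpG of greatest difference in each window. The sign matched in 405 of 425 positive runs and in 48 of 63 negative runs, which differed by Fisher's exact test (two-sided p = 3.99e-06). After the respective medians were subtracted from windows and CpGs, it matched in 390 of 425 positive and 58 of 63 negative runs, and no difference was detected (Fisher's exact test, two-sided p = 1). Across 4434 windows that did not overlap and held at least 3 listed CpGs, the window difference and the CpG mean had a Pearson correlation of 0.627 and a Spearman correlation of 0.587, and the sign was the same in 79.3%. Windows are not independent replicates, and windows and CpGs came from the same calves.

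Single CpG cytosines showed a wider spread of differences than the windows and a weaker excess of positive values. The authors' deposited table of cytosines held 742978 positions from 710244 CpGs, 370604 on the plus strand and 372374 on the minus strand. The median difference was 2.13 percentage points, with an interquartile range of -2.19 to 6.61, and 63.1% of the differences were positive. At a q-value below 0.05, 94706 cytosines (12.7%) were called in the authors' deposited table, 69115 positive and 25591 negative. With differences of at least 25 percentage points 21600 remained (56.0% positive), and with at least 50 percentage points 2530, of which 1458 were positive and 1072 negative. Subtracting the median balances the signs of all cytosines by construction. Relative to it, 46.4% of the called cytosines were positive, against 73.0% as deposited. With the error multiplied by the scatter between strands, 17492 cytosines were called at an adjusted p-value below 0.05, and 58.3% of them were positive.

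The greatest positive differences of single cytosines in the authors' deposited table were 90.6 percentage points on chromosome 24 at 55294837 (the authors' q = 1.52e-36), 89.6 on chromosome 4 at 56571724 and 88.4 on chromosome 10 at 92671914. A second cytosine on chromosome 24, at 55294810, had a difference of 86.6 percentage points in the authors' deposited table. Chromosome 22 at 454897 had the greatest negative difference in the authors' deposited table, with -85.4 percentage points (the authors' q = 3.16e-55), followed by chromosome 24 at 49093886 with -84.3 and chromosome 1 at 101953754 with -82.3. Other listed CpGs near these sites mostly had small differences. Within 250 bp, the single other listed CpG differed by 1.52 percentage points at the site on chromosome 10, by 7.25 at the site on chromosome 22 and by 0 at the negative site on chromosome 24. At 102006164 and 102006236 on chromosome 1, both cytosines were strongly negative in the authors' deposited table, at -81.3 and -81.2 percentage points. For none of the cytosines named here was the cytosine on the opposite strand listed.

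At the 32734 CpGs listed on both strands, the differences of the strands had a Pearson correlation of 0.540 and a Spearman correlation of 0.238 across CpGs, which are not independent replicates. The median absolute difference between strands was 5.87 percentage points. Called cytosines with at least 50 percentage points and a listed partner on the opposite strand numbered 245, and the partner had the same sign in all of them, with a median ratio of the differences of 0.906. At listed CpGs 2 to 10 bp from such a site, the median ratio was 0.0689 over 146 pairs of a site and a listed CpG. For called CpGs with differences of 10 to 25 percentage points, the ratio 2 to 10 bp away was 0.492, and it fell to 0.162 at 51 to 100 bp. Relative to the median difference, these ratios were 0.425 and 0.1004, so that part of the ratio at the greater distance came from the positive shift of all CpGs. The agreement of the strands was weaker for smaller differences. Among all 9180 called cytosines with a listed partner, the sign was the same in 78.7%, and the median ratio was 0.497. With at least 10 percentage points (7678 cytosines) this ratio on the opposite strand was 0.528. It was not computed for 10 to 25 percentage points alone.

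**Figure D3:**
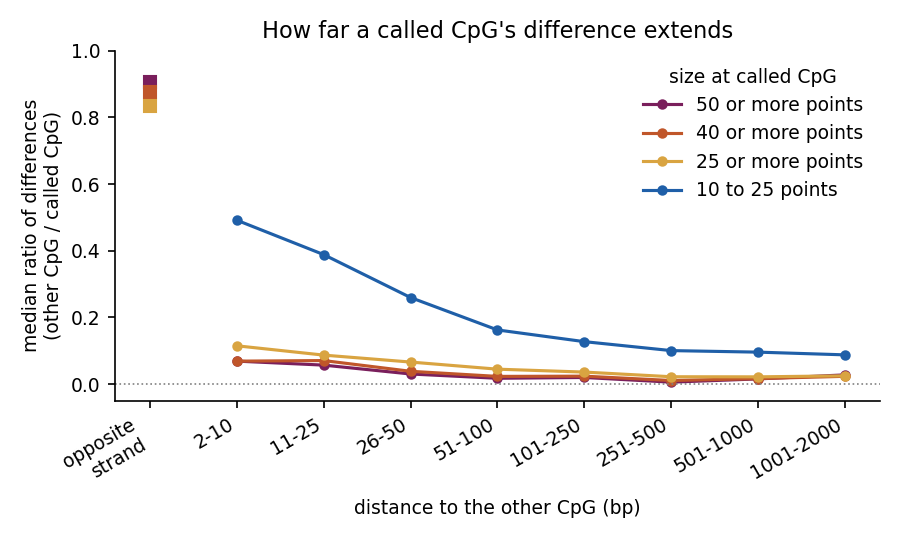
Median ratio of the difference at a second CpG to the difference at a called CpG (y axis) by the distance between them in bp (x axis), for 4 sizes of the difference at the called CpG in percentage points; squares give the opposite-strand cytosine of the same CpG. Sites of 50 points or more have a ratio of 0.906 on the opposite strand and 0.0689 at CpGs 2 to 10 bp away, where sites of 10 to 25 points have 0.492.

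The positive differences extended over all chromosomes. All 30 chromosomes had a positive median of the window differences, from 2.73 percentage points on chromosome 6 to 3.89 on chromosome 27, and of the cytosine differences, from 1.62 on X to 2.31 on chromosome 18. Entries on X ended at 11116754, and the rest of this chromosome was not analysed here. Over this part the cytosine median was below the autosomal median of 2.13, with a difference of X minus autosomes of -0.514 percentage points (95% interval of a bootstrap over 1 Mb blocks, -0.934 to -0.118), and 6 of 208 autosomal stretches of the same length had a median at or below it. The listed part is the start of X, and among the first stretches of the 29 autosomes 2 had a median at or below it, with a lowest value of 1.51. By distance from the chromosome start, the cytosine medians were 2.17 in the first 0.1 Mb, 1.91 from there to 1 Mb, 1.93 from 1 to 5 Mb, 2.08 from 5 to 20 Mb and 2.16 beyond. For windows the interval of X minus autosomes, -1.35 to 0.0241, included 0. The share of runs with a difference of 10 percentage points or more was 8.09% on chromosome 13 (31 of 383) and 8.15% on chromosome 19 (22 of 270), and no chromosome passed the threshold after Benjamini-Hochberg adjustment over 30 chromosomes (Fisher's exact test, smallest adjusted p = 0.138, on chromosome 13; unadjusted p = 0.00459).

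**Figure D4:**
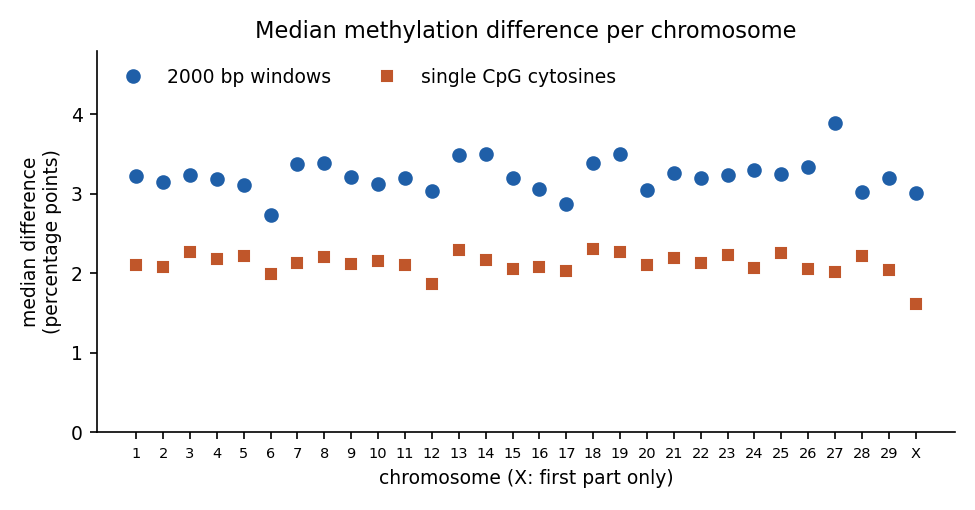
Median methylation difference between the BHB groups (y axis, percentage points) of windows (blue circles) and single cytosines (orange squares) on each chromosome (x axis; X only as far as listed). All medians are above 0, from 2.73 to 3.89 for windows and from 1.62 on X to 2.31 for cytosines.

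The p-values and q-values behind these calls are the authors' own, and the spread between calves within a group could not be set against any difference. Birth season differed in part between the BHB groups, and without values per calf the season and the group cannot be told apart.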

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

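Stricter thresholds and the removal of X were planned before the data were examined, and the other alternatives were chosen after seeing the data. The 84653 called windows became 3071 with at least 10 percentage points and 15 with q below 0.01 and at least 25, by the construction of these thresholds. Relative to the median difference 37038 windows were called and 50.9% of them were positive, against 93.0%. Calls relative to the median, or with a multiplied error, use a Benjamini-Hochberg adjustment rather than the authors' q-value. This adjustment alone called 74794 windows and 84178 cytosines. The 94706 called cytosines became 47488 with q below 0.01, 21156 with q below 0.01 and at least 25 percentage points (56.0% positive, against 73.0%) and 17492 with the error multiplied by the scatter between strands (58.3% positive). Relative to the median, 46.4% of the called cytosines were positive. Subtracting the median balances the signs of all differences by construction, though not exactly those of the called ones. It removes the common shift, so neither share shows a change of direction. Autosomes alone, the Benjamini-Hochberg adjustment, windows without overlap, single strands and the other summaries, 30 values in all, kept their direction and moved less than 1.5 times, except the ratio at CpGs 2 to 10 bp from large CpG differences (0.0689, and 0.115 with a threshold of 25 percentage points). Of the values from listed CpGs inside named windows, 13 moved little, 19 moved further without a change of sign, and 7 were reversed. The reversed values, without and with removal of the CpG of greatest difference, were 5.38 and 3.52 on chromosome 28. On chromosome 2 they were 0.973 and 3.97, and at 23166301 on chromosome 8 they were 11.1 and 9.20. On chromosome 27 the value without removal was 1.09. The cause was not tested. On chromosome 28 the listed CpGs lay only near the end of the window, so their mean does not stand for the whole of it. No paired analysis was possible because the deposited comparisons hold no values per calf. For the same reason the planned count models, left-out calves, other splits, birth date covariate and coverage limits were not run, nor were contexts and gene lists, which also need annotation of this assembly. Unknown depth limits every named value.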

Other observations

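All tests below were chosen after the results they bear on had been seen, except the tests of pairs of large CpG differences along the chromosomes, of clustering of strong runs, and of strong runs near large CpG differences with shuffles within chromosomes, whose predictions were written before their results. The shuffles matched on nearby listed CpGs and the subset of 511 runs had no prediction.

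A small part of the CpGs with large differences lay in dense groups. Averaged over strands, 2392 CpGs differed by at least 50 percentage points, 0.337% of the listed CpGs, and 994 of 2513 stretches of 1 Mb held at least 1 of them. In 16 stretches there were 10 or more, together 209 CpGs or 8.74% of the total, and the rest lay elsewhere. On chromosome 7 the stretch from 41000001 to 42000000 held 19 such CpGs (7.82% of 243 listed) and the next, to 43000000, held 18 (7.53% of 239), while the medians over their listed CpGs were 2.18 and 1.74 percentage points. Chromosome 1 had 17 such CpGs between 100000001 and 101000000 and 18 between 102000001 and 103000000. The stretch of chromosome 13 from 21000001 to 22000000 held 14, and the window of greatest positive difference in the authors' deposited table lies in it. The stretches were ranked after their values were seen. In many of them both signs occurred, with 10 positive and 9 negative at 41000001 on chromosome 7, whereas 10 of 11 were negative between 82000001 and 83000000 on chromosome 1.

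The starts of the chromosomes held many tested windows. In the first 0.1 Mb, 24 runs held 1195 windows, of which 97.8% had a positive difference in the authors' deposited table, with a median of 3.56 percentage points. These windows overlap, and runs on chromosome 23 from 1 to 29900 and from 35601 to 54600 held 244 and 171 windows. The 412 cytosines listed there showed no such excess, with 60.9% positive and a median of 2.17 percentage points, against 63.4% positive beyond 20 Mb. Windows and cytosines were spread unequally, since windows of the run from 1 to 29900 held at most 1 listed CpG. The longest run of windows extended over 80300 bp on chromosome 14 from 13755201 to 13835500, with differences from 1.97 to 8.10 percentage points in the authors' deposited table and a median of 4.21.

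Where a partner was listed, differences of 50 percentage points or more at single CpGs were present on both strands (245 called cytosines, median ratio of 0.906), which argues against counting error on a single strand. With CpGs listed 2 to 10 bp away, the median ratio of 0.0689 over 146 pairs argues against a regional methylation difference for most such pairs. This does not hold for the 59 of 530 sites (11.1%) whose neighbours within 50 bp carried at least 0.5 of the difference. A sequence variant at the CpG remains a candidate explanation that both ratios allow, since bisulfite reads show a C-to-T or G-to-A allele as loss of methylation. Pairs of such CpGs 1 to 100 kb apart numbered 1513, 4.74 times the mean of the shuffles (319, with a highest of 398). Of these pairs, 68.0% shared a sign, against 51.9% in the shuffles. Variants on haplotypes that differ in frequency between the groups would give such a pattern. Other local grouping of these CpGs would also raise the ratio, since the shuffles placed each CpG independently. The ratio cannot decide between these causes. Genotypes were not analysed here, mapping errors in particular regions were not tested, and a methylation difference at isolated CpGs between the BHB groups stays open as well.

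Runs with a difference of 10 percentage points or more lay closer to these CpGs than other runs did. A CpG of at least 50 percentage points was present 1 to 100 kb outside the run in 145 of 597 such runs (24.3%) and in 13.2% of the other runs, 1.69 times the mean of the shuffles and above the highest of them, 122. With shuffles among runs with similar numbers of listed CpGs nearby, the ratio was 1.70, and for the 511 runs with no such CpG inside or within 1 kb it was 1.43 (96 against a highest of 89), below the 1.5 times set for the first test. A candidate explanation is that part of the regional differences follow haplotypes shared by calves of a group, although most of these runs had no such CpG nearby. Neighbouring runs of the same sign within 1 Mb numbered 136, against a mean of 115 in the shuffles (one-sided permutation p = 0.0091).

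The positive shift of most windows was examined by subtracting the median. Of 105161 windows whose p-value gave an error, 35.2% then had an adjusted p-value below 0.05. A shift of equal size with counting error would leave few, but only if the authors' p-values give the error correctly. No window test with a wider error was run, so a shift of equal size with further spread stays possible. The differences of opposite strands scattered 1.44 times as widely as the authors' p-values imply, so that these p-values may be too small, and spread between calves, which this scatter reflects at most in part, was not measured. Library preparation, bisulfite conversion and blood cell composition cannot be told apart from the BHB groups as sources of the median shift of 3.23 percentage points, because no value per calf bears on them. A difference between the BHB groups themselves, and the birth season, stay open and untested.

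A p-value of 0 was listed for 226 windows in 6 runs of the authors' deposited table, 90 of them on chromosome 2 from 121565101 to 121577900, 84 on chromosome 27 from 6216901 to 6227800 and 23 on chromosome 18 from 59223401 to 59227600, with medians of 10.4, 12.1 and 13.1 percentage points, and the others on chromosomes 21, 4 and 16, with medians of 4.05, 4.97 and 3.19. A greater difference alone is argued against by the error these p-values allow, at most 0.390 percentage points, below the 2.5th percentile of 0.463 in other windows. Reads of a multi-copy sequence stacked on a single copy may explain them, since these windows held 0.00634 times as many listed CpGs as other windows, and 219 of them held none. Whether these regions are repeated in the genome was not tested, and no biological explanation was tested.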
